A study of Mus musculus with 4 samples.

How the data were processed

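CD4 T cells from mesenteric lymph nodes (mLN) of male mice of the Foxp3GFP and Foxp3CNS1- strains were profiled by single-cell RNA sequencing with 10x 3′ v3 chemistry, per the labels' protocols. CNS1 is an intronic enhancer of Foxp3 that takes part in the induction of regulatory T (Treg) cells outside the thymus. The mice were germ-free or had received fecal microbiota of specific-pathogen-free mice 9 days before. Each library came from a pool of 3 mice and held GFP-positive and GFP-negative cells sorted in equal parts, with about 5000 cells targeted. There were 4 groups with 1 library each.

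The deposited table holds UMI counts that the authors made with Cell Ranger and Scanpy 1.5.1 on the mm10 build, per the submitters' processing notes. The Cell Ranger version and the cell and gene filters are not given in the sources used here. All values were checked to be whole numbers of at least 0. The table had 17478 cells and 13314 genes. A second deposited table gave the library and cluster number of 17251 cells, and the other 227 cells were not used. A further 303 cells that the authors had marked as removed were left out, which left 16948. In the removed cells Ccl5 had 15693 CPM (UMI counts scaled to the total of the cells named) against 71.4 in the analysed cells, and Cd74 had 12542 against 149. Of the cell table, 3 columns were not used.

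The authors' 10 clusters, which carry numbers only, were given names from marker lists fixed before the data were examined. The leading genes of a cluster had a UMI in at least 10% of its cells. Clusters 0, 3 and 6 were called Treg-like and clusters 1 and 2 naive-like. Cluster 5 stayed unnamed and was added as a class after its values were seen. Clusters 4, 7, 8 and 9 entered no class. Cluster 4 held 15.8% of the germ-free Foxp3GFP, 11.4% of the colonized Foxp3GFP, 10.7% of the germ-free Foxp3CNS1- and 7.01% of the colonized Foxp3CNS1- cells. In the same order cluster 7 held 7.09%, 4.02%, 4.70% and 2.05%, cluster 8 held 2.66%, 4.32%, 2.38% and 5.11%, and cluster 9 held 0.628%, 0.447%, 0.481% and 0.444%. Cluster sizes were not compared between libraries, because the leading genes of the clusters examined also differed between libraries in the other cells.

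A separate Leiden clustering (scanpy 1.11.5, leidenalg 0.10.2, 1500 variable genes, 30 principal components, 20 neighbours, resolutions 0.5 and 2) was used for alternatives. Its rule for naming clusters was settled after a first set of names had been seen. At resolution 0.5 it placed part of the Treg-like class in a cluster led by Sostdc1 and Il4 and called here follicular-helper (Tfh)-like. These were 11.6% of the class in germ-free Foxp3GFP, 11.9% in colonized Foxp3GFP, 26.0% in germ-free Foxp3CNS1- and 15.8% in colonized Foxp3CNS1-. Scrublet marked 2 of 16948 cells, or 0.0118%, too few for its calls to be taken as working. Whether doublets had been removed earlier is not given in the sources used here, and no cell was left out as a doublet.

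Counts were summed per library and class and scaled to CPM of that class and library. A ratio was computed for genes with at least 50 UMIs over both libraries, with an exact 95% interval (Clopper-Pearson) that covers counting error only. It does not cover differences between mice, between libraries or between cells, and it is too narrow where few cells hold most UMIs. Against a count of 0 the ratio was taken to a floor of 3 counts. Shares of cells carry exact binomial intervals. Each group has 1 library, so the comparisons between groups have no replicate and no test was made. A model that adds up genotype and colonization over the 4 libraries was not fitted. The genes named were up to 8 per direction, comparison and class whose interval bound nearest to 1 was farthest from it. T cell receptor, immunoglobulin, ribosomal protein, mitochondrial, Y-linked and predicted genes and Xist were left out of that ranking. The text names part of them. Genes outside it, such as members of the lists, were picked as examples after their values were seen.

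The median log2 ratio of each of 24 gene lists, fixed before the data were examined, was set beside the central 95% of 10000 random lists matched on mean expression. That range describes these libraries only. The lists printed are a choice, and the number outside the range is given below for each comparison in Treg-like cells. In naive-like cells it was 9 of 22 lists under colonization in Foxp3GFP and 15 of 22 in Foxp3CNS1-. By genotype it was 8 of 22 in germ-free and 6 of 23 in colonized mice. For the difference of the colonization ratio between genotypes it was 7 of 22. In cluster 5 these counts were 16 of 22, 14 of 24, 8 of 20, 6 of 24 and 6 of 22 in the same order.

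The calculation was tested on simulated data with 200 genes changed by a fold of 2 in each comparison. For the colonization comparison in Foxp3GFP Treg-like cells, over 8075 genes, the median fold recovered for raised genes was 1.99, and the interval held the true ratio for 93.5% of changed genes. Over all comparisons and classes that share was 93.5% to 97%. The interval is built for counting error, so such shares follow by design where counts vary by counting error alone. They check the calculation only. They do not show how often the interval holds the true ratio in the deposited data, where mice and cells differ and few cells can hold most UMIs of a gene.

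The alternatives were centring on the median gene, equal weight per cell, thinning every cell to 1459 UMIs, minimums of 1 and 200 UMIs, all cells with a Foxp3 UMI in place of the Treg-like class and all cells without one in place of the naive-like class, a fixed cluster mix, and a filter of at least 1000 genes and under 5% mitochondrial counts. Others were added after the data were seen and left out cells with at least 10 immunoglobulin UMIs, cells above the 98th percentile of UMIs, cells with Hspa1a or Hspa1b UMIs, Treg-like cells without a Foxp3 UMI, naive-like cells with one, or Tfh-like cells, or held the mix of the authors' second clusters fixed in cluster 5. Named genes were at first followed only above the count minimum, which hid genes whose UMIs lay in the cells left out. They are now followed at any count above the floor. Levels within the Tfh-like cells alone were taken after the data were seen. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.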

Results

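Single-cell UMI counts were obtained for mLN CD4 T cells of 4 groups of mice, with 1 library per group. The germ-free Foxp3GFP library had 3979 analysed cells and 10746648 UMIs, and the colonized Foxp3GFP library had 4030 cells and 13437705 UMIs. The germ-free Foxp3CNS1- library had 3533 cells and 9360112 UMIs, and the colonized Foxp3CNS1- library had 5406 cells and 17929193 UMIs. Median UMIs per cell were 2399, 2832, 2286 and 2764 in this order. No value below has a replicate, and library, batch and group cannot be told apart.

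Foxp3 (mm10 chromosome X, 7573644 to 7595245) was the targeted gene. In Treg-like cells it had 159 CPM in germ-free Foxp3GFP, 177 in colonized Foxp3GFP, 146 in germ-free Foxp3CNS1- and 161 in colonized Foxp3CNS1-. In naive-like cells Foxp3 had 30.3, 25.6, 30.2 and 13.7 CPM. The colonization log2 ratio of Foxp3 in Treg-like cells was 0.16 (-0.0038 to 0.32) in Foxp3GFP and 0.14 (-0.016 to 0.29) in Foxp3CNS1-. After thinning the Foxp3GFP value was 0.35 (0.11 to 0.58), an interval that left out 0. Without Tfh-like cells the Foxp3CNS1- value changed sign to -0.016 (-0.17 to 0.14). Both values changed sign among cells taken by a Foxp3 UMI, a choice that removes a difference in the share of such cells. The genotype log2 ratio of Foxp3 in Treg-like cells was -0.12 (-0.30 to 0.06) in germ-free and -0.14 (-0.27 to -0.0066) in colonized mice. Without Tfh-like cells the germ-free value was 0.16 (-0.025 to 0.34), of the other sign, and both intervals held 0. The colonized value was then -0.075 (-0.21 to 0.058). Its interval also held 0 after thinning, at -0.18 (-0.37 to 0.013), and with the stricter cell filter, at -0.076 (-0.23 to 0.077). Counts at the 3′ end of Foxp3 do not read the enhancer deletion, so they do not check the genotype.

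A Foxp3 UMI was found in 30.02% (27.5 to 32.7) of germ-free and 34.9% (32.4 to 37.3) of colonized Foxp3GFP Treg-like cells. The shares were 24.2% (22.0 to 26.4) and 30.9% (29.0 to 32.8) in Foxp3CNS1-. Thinned to equal depth they were 18.7%, 22.4%, 18.2% and 19.6%. The naive-like cells of the same libraries had 7.02%, 5.75%, 6.23% and 3.18%. Thinning left out 397, 162, 338 and 236 cells. Treg-like cells were 31.1% (29.7 to 32.6), 37.7% (36.2 to 39.2), 41.1% (39.5 to 42.8) and 44.7% (43.3 to 46.0) of all cells, and naive-like cells were 37.6%, 33.6%, 31.4% and 25.6%. The sort into equal parts of GFP-positive and GFP-negative cells can set these shares.

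The first comparison asked how colonization of Foxp3GFP mice relates to expression in Treg-like cells. Interferon-stimulated genes were higher in the colonized library: all 29 measured members were higher, with a median log2 ratio of 1.38 against -0.11 to 0.07 for random lists. Ifit3 had 96.8 CPM in colonized against 8.10 in germ-free, a log2 ratio of 3.58 (3.01 to 4.21). Gzmb had 87.6 against 5.30 CPM, a log2 ratio of 4.05 (3.35 to 4.84), and was found in 99 of 1518 colonized and 10 of 1239 germ-free cells. Gzma had 49.1 against 2.49 CPM. The IL-2/STAT5 response list had a median of 0.47 with 11 of 13 members higher, and MHC class I had 0.27 with 11 of 11.

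Other genes were lower in colonized Foxp3GFP Treg-like cells. Cdk5rap1 had 5.26 against 33.7 CPM, Sox4 had 2.63 against 19.3, and Eomes had 2.41 against 15.6. Among Treg-like cells with a Foxp3 UMI Eomes had 2 UMIs against 0. Sostdc1 had 23.4 against 67.6 CPM, and 87.6% of its germ-free UMIs lay in Tfh-like cells. The exhaustion and anergy list had a median of -0.27 with 10 of 12 members lower. The TCR signalling list had -0.25 with 14 of 18 lower, but among cells with a Foxp3 UMI it was 0.067, or -0.048 over the original members, and after thinning it was -0.070, each inside its random range. Of 24 lists, 12 lay outside their random range.

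Jchain, Slpi and Mzb1 ranked highest in this comparison, each through a few cells. Jchain had 539 UMIs against 0, at least 126-fold by the floor, with 97.96% of the UMIs in 3 cells. Slpi had 226 UMIs against 1, a ratio of 159 (28.2 to 6302), and Mzb1 had 127 against 0. Hspa1a had 78 against 3 UMIs, a log2 ratio of 4.19 (2.59 to 6.5). Cells with an Hspa1a or Hspa1b UMI were 0.226% and 9.95% of germ-free and colonized Foxp3GFP cells, and 0.340% and 8.84% in Foxp3CNS1-.

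In the same comparison in Foxp3CNS1- Treg-like cells, all 30 interferon-stimulated genes were higher in the colonized library, with a median of 0.997 against -0.11 to 0.05 for random lists. Gzmb had 86.0 against 4.79 CPM, a log2 ratio of 4.17 (3.48 to 4.96), Ifit3 had 71.5 against 4.79 CPM, and Ifit1 had 101 against 11.8 CPM. The IL-2/STAT5 response list had 0.18 with 10 of 13 members higher, MHC class I 0.12 with 9 of 11, TCR signalling -0.30 with 15 of 18 lower, and exhaustion and anergy -0.30 with 10 of 12 lower. MHC class I was just above its random range and lay inside it at 0.061 with the cluster mix fixed, and at 0.10 with equal weight per cell, without immunoglobulin-rich cells and without cells above the 98th percentile of UMIs. Of 24 lists, 14 lay outside their random range.

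Tfh genes were lower in colonized Foxp3CNS1- Treg-like cells, with a list median of -0.60 and 15 of 18 members lower, against -0.17 with 12 of 16 in Foxp3GFP. Il4 had 16.0 against 69.5 CPM, and Ascl2 had 2.59 against 16.0. Spp1 had 4.17 against 50.4 CPM, but 3 cells held 98.9% of its germ-free UMIs, and without Tfh-like cells it had 3 UMIs in each library. Tfh-like cells were 26.0% of the class in the germ-free and 15.8% in the colonized library, and 93.5% of the germ-free Il4 UMIs lay in them. Within the Tfh-like cells Il4 was lower as well, with 98 UMIs in 381 colonized and 231 UMIs in 378 germ-free cells, and Ascl2 had 12 against 54 UMIs. Without those cells the log2 ratio of Il4 was -1.46 (-2.64 to -0.31), that of Ascl2 was -0.16 (-2.39 to 2.46), and those of Sostdc1 and Xcl1 changed sign to 0.38 and 0.49.

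**Figure D1:**
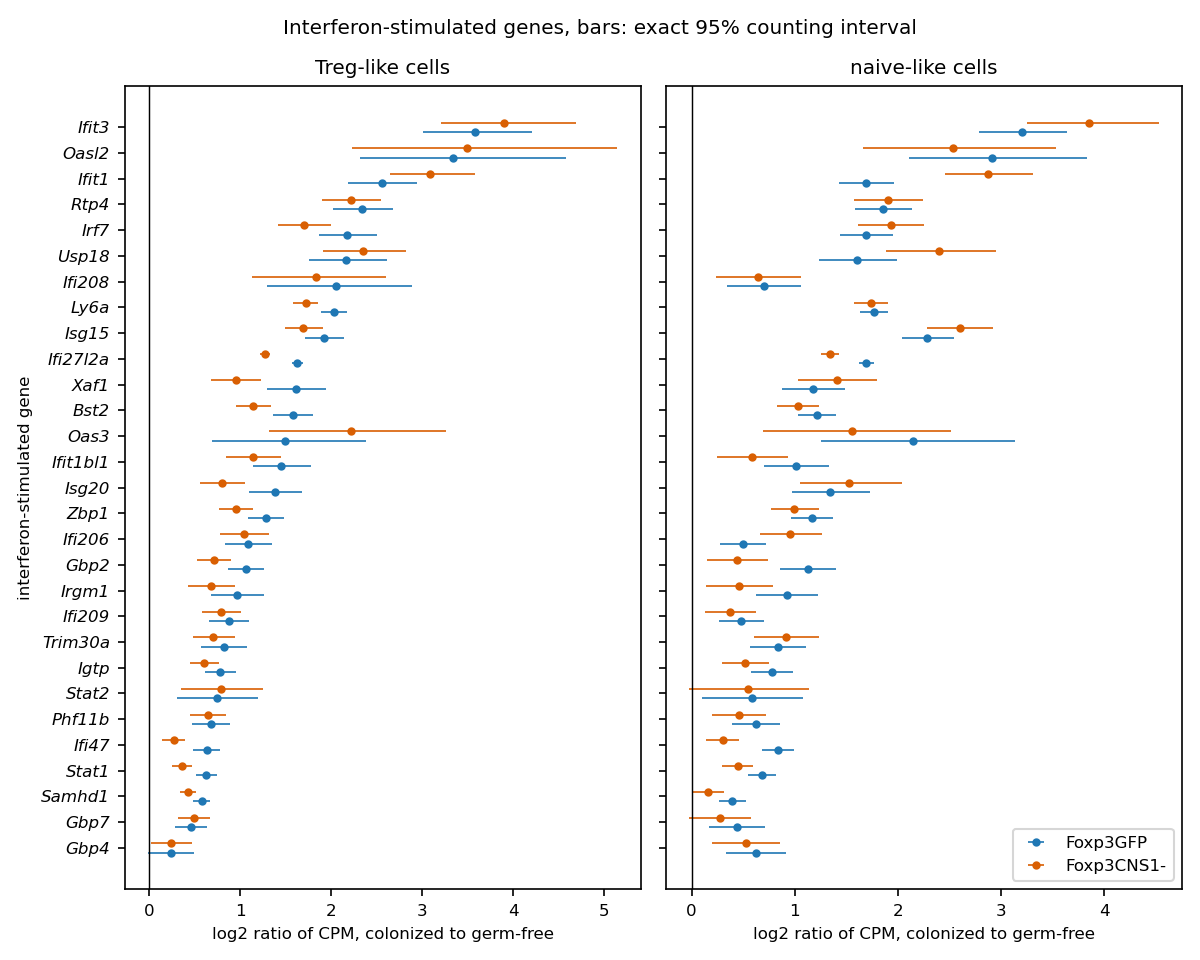
Log2 ratio of CPM, colonized to germ-free, of 29 interferon-stimulated genes in Treg-like and naive-like cells. Points are single libraries compared, bars are exact 95% counting intervals, and all points lie above 0.

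In naive-like cells all 30 interferon-stimulated genes were higher in the colonized library of both genotypes, with medians of 1.15 in Foxp3GFP and 0.98 in Foxp3CNS1-. Isg15 had 191 against 39.2 CPM in Foxp3GFP and 189 against 31.2 in Foxp3CNS1-. Socs3 had 223 against 50.1 CPM in Foxp3GFP. Nr4a1 was lower in colonized Foxp3GFP, at 3.23 against 17.5 CPM. Without the naive-like cells that held a Foxp3 UMI its log2 ratio was -2.28 (-3.27 to -1.40). Over all cells without a Foxp3 UMI, of every cluster, it was -0.14 (-0.45 to 0.17). Dusp2 was lower in colonized Foxp3CNS1-, at 61.7 against 139 CPM. The TCR signalling list had medians of -0.32 and -0.47. The larger naive-like cluster was cluster 2 in both germ-free and cluster 1 in both colonized libraries. In the other cells the leading genes of cluster 1 were lower under colonization, by medians of -0.50 in Foxp3GFP and -0.41 in Foxp3CNS1-. A general fall of these genes would not by itself explain a larger cluster 1. With 1 library per group the split is still not read as an effect of colonization.

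The genotype comparison in germ-free mice asked how the enhancer deletion relates to expression before colonization. In Treg-like cells Il4 had 69.5 CPM in Foxp3CNS1- against 13.7 in Foxp3GFP, Spp1 had 50.4 against 2.18, and Cxcr6 had 40.3 against 11.5. Gzma had 18.0 against 2.49 CPM. Cd55 was lower, at 8.73 against 37.1 CPM, as was Eomes, at 4.22 against 15.6. Among all cells with a Foxp3 UMI the log2 ratio of Eomes was 2.23 (-1.11 to 7.85), and among Treg-like cells with one it had 3 UMIs against 0, so its lower level lay in cells without a Foxp3 UMI. The effector list had a median of 0.46 with 15 of 17 members higher, the Th2 list 1.04 with 4 of 4, and the naive list -0.28 with 9 of 14 lower.

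UMIs of several of these genes lay mostly in Tfh-like cells, which were 26.0% of the class in Foxp3CNS1- and 11.6% in Foxp3GFP. Tfh-like cells held 98.3% of the Spp1 UMIs in Foxp3CNS1-, where 3 cells held 98.9% of all Spp1 UMIs, and 93.5% of the Il4 UMIs. Within Tfh-like cells Il4 had 247.5 against 98.9 CPM. Without Tfh-like cells the log2 ratio of Spp1 changed from 4.53 to -0.89 (-3.52 to 1.34), and that of Xcl1 from 2.32 to -0.25. Il4 changed from 2.34 to 1.52 (0.10 to 3.16), and was at -0.0040 (-1.27 to 1.25) among cells with a Foxp3 UMI. The Tfh list was 0.30 over all cells and 0.11, inside its random range, without them. Gzma at 2.54, Cxcr6 at 2.03, Cd55 at -1.79 and the effector list at 0.48 kept their direction. The effector list was 0.26 after thinning. Of 24 lists, 11 lay outside their random range.

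**Figure D2:**
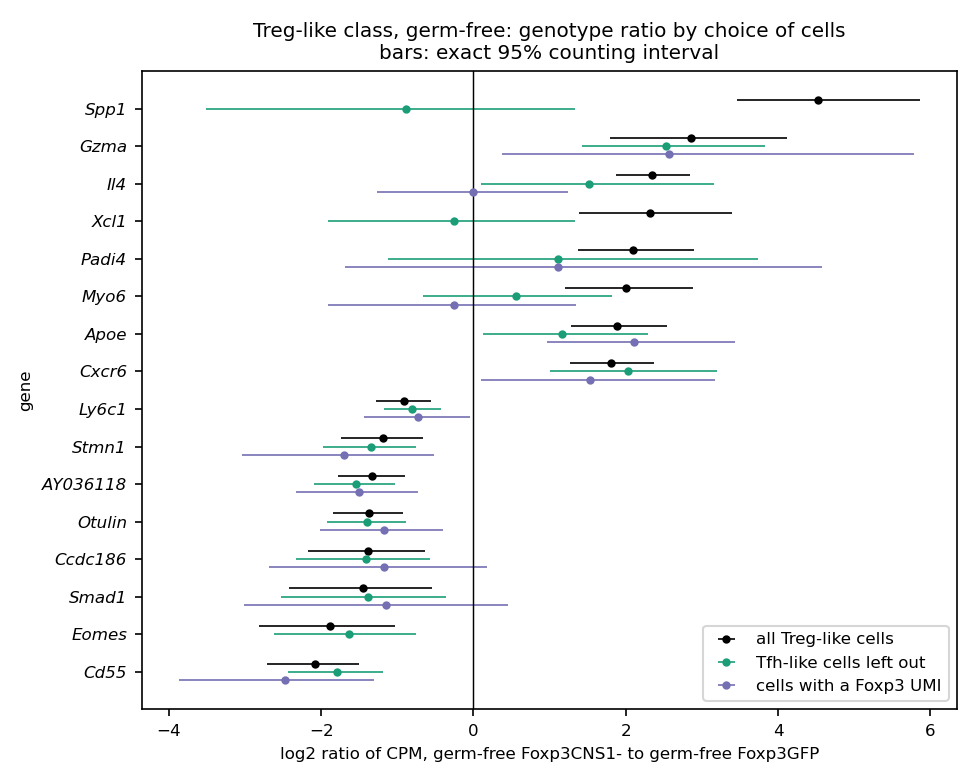
Log2 ratio of CPM, germ-free Foxp3CNS1- to germ-free Foxp3GFP, of the genes named in Treg-like cells, for all cells, without Tfh-like cells, and for cells with a Foxp3 UMI. Bars are exact 95% counting intervals, and Spp1 and Xcl1 change sign without Tfh-like cells.

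In colonized mice the genotype comparison in Treg-like cells gave Gzma at 111 CPM in Foxp3CNS1- against 49.1 in Foxp3GFP, a log2 ratio of 1.17 (0.96 to 1.40). The authors' second clustering held a cluster of 17 cells led by Gzma, 13 in colonized Foxp3CNS1- and 4 in colonized Foxp3GFP. How many of the Treg-like Gzma UMIs lay in that cluster was not counted. Slc15a2 had 12.5 against 1.31 CPM and Cdk5rap1 had 26.5 against 5.26. Gstp1 was lower, at 98.5 against 153 CPM. The interferon-stimulated list was lower, with a median of -0.23 and 28 of 30 members lower, and the Tfh list was higher, at 0.22 with 13 of 17. The Tfh list lay inside its random range at 0.15 among Treg-like cells with a Foxp3 UMI and at 0.10 among all cells with one. The effector list had 0.06, inside its random range, but lay above that range at 0.16 after thinning, 0.25 among cells with a Foxp3 UMI, 0.16 without Tfh-like cells and 0.13 with equal weight per cell. With the cluster mix fixed it was -0.064, just below its range. Of 24 lists, 5 lay outside their range.

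In naive-like cells H2-DMa was higher in Foxp3CNS1- in both states, at 220 against 89.8 CPM in germ-free and 199 against 98.6 in colonized mice. Ppp3cc had 66.8 against 36.0 and 58.3 against 30.1 CPM. In germ-free Foxp3CNS1- naive-like cells Ifit1 was lower, at 17.6 against 38.5 CPM, and Cd55 was lower, at 24.4 against 50.1. The Treg core list was lower in colonized Foxp3CNS1-, with a median of -0.59 and 14 of 15 members lower, and Ctla4 had 9.55 against 21.1 CPM. Without the naive-like cells that held a Foxp3 UMI the list was -0.28, below its random range, and Ctla4 was at a log2 ratio of -0.76 (-1.43 to -0.10). Over all cells without a Foxp3 UMI, of every cluster, the direction was the other: the list was 0.19, above its random range, and Ctla4 was 0.11 (-0.017 to 0.25). That set was 3186 cells in colonized Foxp3GFP and 4332 in colonized Foxp3CNS1-, of which 1278 and 1339 were naive-like. It also held the Treg-like cells without a Foxp3 UMI, so its values do not read naive-like cells alone. Across genes, which are not independent replicates, the genotype ratios in germ-free and colonized mice had a Pearson r of 0.13 in Treg-like and 0.08 in naive-like cells.

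The difference between genotypes in their colonization ratio compared both colonization effects. The interferon-stimulated list was lower in Foxp3CNS1-, by a median of -0.17 in Treg-like cells with 21 of 29 members lower. In naive-like cells it was -0.13, but inside its random range under 5 alternatives. These were -0.11 after thinning and without cells holding an Hspa1a or Hspa1b UMI, -0.10 with at least 200 UMIs per gene, -0.095 without naive-like cells holding a Foxp3 UMI and 0.048 with the stricter cell filter. The effector list differed by -0.29 in Treg-like cells, from a median of 0.21 in Foxp3GFP and -0.08 in Foxp3CNS1-, but by -0.089, inside its random range, among cells with a Foxp3 UMI. The Foxp3GFP median lay inside its range at 0.042 with the cluster mix fixed and 0.055 without immunoglobulin-rich cells. The Foxp3CNS1- median was 0.18 with at least 200 UMIs per gene, 0.17 among all cells with a Foxp3 UMI and 0.11 among Treg-like cells with one. Over the original members it was -0.076 with at least 200 UMIs and -0.036 among Treg-like cells with a Foxp3 UMI. It was -0.20, below its random range, both with the cluster mix fixed and without immunoglobulin-rich cells. The Treg core list differed by -0.56 in naive-like cells, where it had a colonization median of -0.78 in Foxp3CNS1-. Without the naive-like cells that held a Foxp3 UMI that median was -0.67, below its random range. Over all cells without a Foxp3 UMI, of every cluster, it was -0.073, inside its random range. Of 24 lists, 11 lay outside their random range in Treg-like cells. Across genes the colonization ratios of both genotypes had a Pearson r of 0.60 in Treg-like and 0.46 in naive-like cells.

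Cluster 5, led by S100a4, Ccr2 and S100a6, was examined after its values were seen. Gzmb had 355 CPM in colonized and 0 UMIs in germ-free Foxp3GFP cells, at least 63.4-fold higher, and 160 against 7.22 CPM in Foxp3CNS1-. The list of genes associated with peripherally induced Treg cells had a colonization median of 1.26 in Foxp3GFP with 6 of 6 members higher, and of -0.08 in Foxp3CNS1- with 3 of 6. Its difference was -1.34, with 5 of 5 members lower. Among cluster 5 cells with a Foxp3 UMI that difference was -0.98 over the same 5 members. This median was the value of Gzmb, whose 0 UMIs in both germ-free libraries put both its ratios at the floor. Maf was at -1.44 on 11 germ-free Foxp3GFP UMIs, and Lag3 at -3.81 and Itgae at -0.36 on 7 each. Ccr9 then went the other way, at 0.57, on 12 germ-free UMIs in Foxp3GFP and 5 in Foxp3CNS1-. In Treg-like cells the difference of this list was -0.046, inside its random range. By genotype it was 0.32 in germ-free Treg-like cells with 6 of 7 members higher, but inside its range under 5 alternatives, such as 0.19 with equal weight per cell. In colonized Treg-like cells it was -0.027, inside its range, and below it at -0.19 with the cluster mix fixed and -0.25 among all cells with a Foxp3 UMI. Its sign there changed under 7 alternatives. In cluster 5 Lag3 had 323 against 118 CPM in Foxp3GFP and 165 against 153 in Foxp3CNS1-. Ccr9 had 79.2 against 46.7 and 30.1 against 48.1 CPM. The cluster 5 difference was -0.26, inside its random range, when all 12 members with any UMI were counted. In Foxp3GFP the colonization median without cells of at least 10 immunoglobulin UMIs was 0.44 on 5 members and 0.88 over the original 6.

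The Th17 list had a colonization median of 1.49 in Foxp3CNS1- cluster 5 cells with 7 of 7 members higher, and differed from Foxp3GFP by 0.98. Between colonized libraries Mmp9 was lower in Foxp3CNS1-, at 4.66 against 44.2 CPM, and Plac8 was lower, at 170.5 against 338. Gzma was higher, at 96.0 against 13.3 CPM, with 78.4% of its Foxp3CNS1- UMIs in 3 cells. Lyz1 had 310 UMIs against 0, all in 2 cells.

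**Figure D3:**
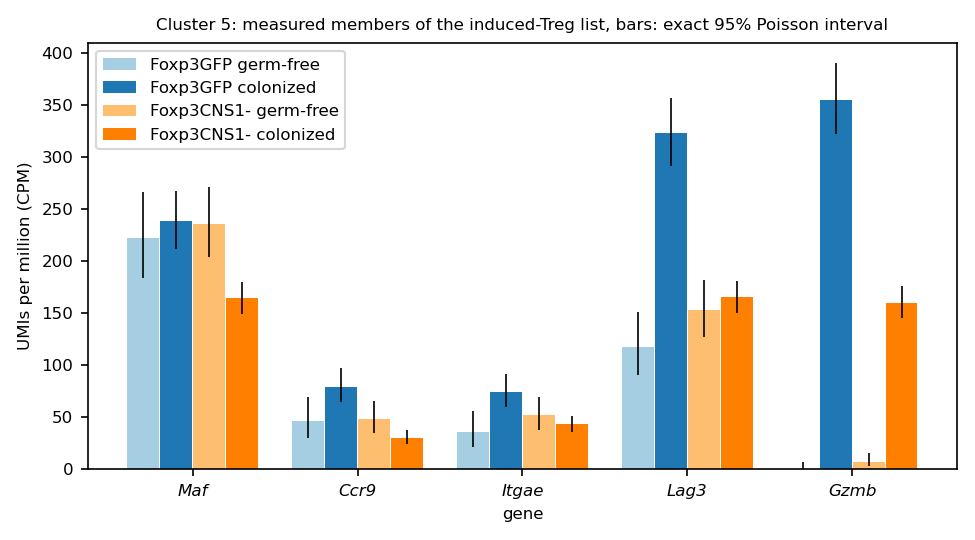
CPM of the 5 measured genes of the peripherally induced Treg list in cluster 5, by library. Bars are sums over 1 library each with exact 95% Poisson intervals, and Gzmb reaches 355 CPM in colonized Foxp3GFP.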

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

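No test was planned in this part. The measures below were chosen after the values were seen, and no explanation was tested.

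Immunoglobulin segment genes were left out of the ranking for named genes. Over all analysed cells their CPM were higher in colonized than in germ-free mice, which drew attention because the sort was for CD4 T cells. The ratio was 2.20 (2.15 to 2.26) in Foxp3GFP and 2.47 (2.41 to 2.54) in Foxp3CNS1-, from 700 to 1542 and from 786 to 1944 CPM. The 10 cells with the most immunoglobulin UMIs held 52.3% of them in the colonized Foxp3GFP library and 58.0% in the colonized Foxp3CNS1- library, against 3.684% and 3.601% in germ-free. The median in cells with any such UMI was 2 in each library.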

How the results depend on the processing

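The alternatives without Tfh-like cells, with a Foxp3 UMI only, without naive-like cells holding a Foxp3 UMI, without immunoglobulin-rich, UMI-rich or Hspa1a and Hspa1b cells, and with a fixed second-cluster mix were chosen after the data were seen. Over 249 results and 17 alternatives, 2251 values stayed within the range allowed, 264 moved by more and 30 changed the sign of a result whose interval left out 0 or whose list median lay outside its random range. A further 23 sign changes, of Foxp3, the effector list and the induced Treg list, were of results without such a call and are counted as within the range or moved. The range allowed was the interval for genes and shares, and 0.5 times the width of the random range to either side for lists. The colonization medians of the interferon-stimulated list stayed between 0.81 and 1.43 in both named classes under each alternative run. Log2 values follow, and the cause was not tested unless stated.

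With every cell thinned, the interferon-stimulated list under colonization in Foxp3GFP was 1.07 in Treg-like (1.33 over its original members) and 0.99 in naive-like cells. In Treg-like cells the effector list by genotype was 0.26 in germ-free and 0.16 in colonized, the latter now above its random range, TCR signalling under colonization in Foxp3GFP was -0.070, inside its random range, and Foxp3 was 0.35. The induced Treg list in cluster 5 of Foxp3GFP was 0.96.

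With at least 200 UMIs per gene, which leaves fewer members, the interferon-stimulated list in Treg-like cells was 1.19 in Foxp3GFP and 0.88 in Foxp3CNS1-. The effector list was 0.33 by genotype in germ-free, 0.18, with changed sign, under colonization in Foxp3CNS1- (-0.076 over its original members), and its difference was -0.15. With at least 1 UMI, the effector list by genotype in germ-free was 0.34, and in cluster 5 the induced Treg list was 0.61 in Foxp3GFP with a difference of -0.26, inside its random range.

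With all cells that hold a Foxp3 UMI in place of the Treg-like class, and all others, of every cluster, in place of the naive-like class, the interferon-stimulated list was 1.21 in Foxp3GFP cells with a Foxp3 UMI and 0.81 in Foxp3CNS1- cells without, where its difference was -0.25. In cells with a Foxp3 UMI the effector list was 0.32 by genotype in germ-free, 0.67 under colonization in Foxp3GFP and, with changed sign, 0.17 in Foxp3CNS1-. The Tfh list by genotype was 0.13 in germ-free and 0.10 in colonized, and TCR signalling in Foxp3GFP was -0.075, all inside their random ranges. Foxp3 changed sign in all 4 comparisons, to -0.067 and -0.14 under colonization in Foxp3GFP and Foxp3CNS1- and to 0.17 and 0.10 by genotype in germ-free and colonized. Taking cells by their Foxp3 UMIs removes a difference in the share of such cells, so neither these values nor those of Foxp3 in the next paragraph test its level. Signs also changed under colonization in Foxp3CNS1- for Mzb1 (-0.71) and Xcl1 (0.20). By genotype in germ-free they changed for Xcl1 (-0.77), Padi4 (-0.093), Myo6 (-0.19) and Eomes (2.23), and in colonized for Lyz2 (-0.42) and Car2 (-0.12). In the cells without a Foxp3 UMI by genotype in colonized they changed for the Treg core list (0.19), Socs2 (0.23), Nudt4 (0.018), Ctla4 (0.11) and Rgs1 (0.19). The Treg core list under colonization in Foxp3CNS1- was -0.073, inside its random range. This set holds many more cells than the naive-like class. With only the naive-like cells that held a Foxp3 UMI left out, no sign changed. The Treg core list was then -0.67 under colonization in Foxp3CNS1-. By genotype in colonized the list was -0.28, Ctla4 -0.76 and Rgs1 -0.35.

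Among Treg-like cells with a Foxp3 UMI, the effector list was 0.25 by genotype in colonized, above its random range, and 0.11 under colonization in Foxp3CNS1- (-0.036 over its original members), with a difference of -0.089, inside its range. The Tfh list by genotype was 0.13 in germ-free and 0.15 in colonized, both inside their ranges. Signs changed for that effector list in Foxp3CNS1- and for TCR signalling under colonization in Foxp3GFP (0.067, or -0.048 over its original members). Foxp3 changed sign under colonization in Foxp3GFP (-0.0034) and Foxp3CNS1- (-0.10) and by genotype in germ-free (0.14) and colonized (0.044). So did Mzb1 (-0.79) and Cxxc5 (0.79) under colonization in Foxp3CNS1-, Il4 (-0.0040) and Myo6 (-0.25) by genotype in germ-free, and Lyz2 (-1.65) and Car2 (-0.88) in colonized.

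Without Tfh-like cells, the effector list by genotype in colonized was 0.16, above its random range, and in germ-free the Tfh list was 0.11, inside its range. Signs changed under colonization in Foxp3CNS1- for Foxp3 (-0.016), Sostdc1 (0.38) and Xcl1 (0.49), and by genotype in germ-free for Foxp3 (0.16), Spp1 (-0.89) and Xcl1 (-0.25). The UMIs of Sostdc1, Xcl1 and Spp1 lay mostly in the cells left out in germ-free Foxp3CNS1-.

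With the stricter cell filter, the interferon-stimulated list was 1.28 in Foxp3GFP and 1.15 in Foxp3CNS1- Treg-like cells, and its naive-like difference changed sign to 0.048. The effector list under colonization in Foxp3GFP was 0.34, and the induced Treg difference in cluster 5 was -0.94. Treg-like cells were 33.5% of germ-free Foxp3GFP, and naive-like cells were 29.4% of colonized Foxp3GFP, 28.4% of germ-free Foxp3CNS1- and 21.98% of colonized Foxp3CNS1-.

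With the cluster mix fixed, the effector list was 0.34 by genotype in germ-free, -0.064, with changed sign, in colonized, just below its random range, and 0.042 and -0.20 under colonization in Foxp3GFP and Foxp3CNS1-. Without cells of at least 10 immunoglobulin UMIs it was 0.055 and -0.20 under colonization, and the induced Treg list in cluster 5 of Foxp3GFP was 0.44 (0.88 over its original members). In Foxp3GFP the effector list entered its random range under both settings, and in Foxp3CNS1- it left it. MHC class I under colonization in Foxp3CNS1- was inside its range at 0.061 with the cluster mix fixed, and at 0.10 with equal weight per cell, without immunoglobulin-rich cells and without UMI-rich cells. That induced Treg list was 0.86 with equal weight per cell and 0.76 with the second-cluster mix fixed. Without cells above the 98th percentile of UMIs, signs changed for Slpi under colonization in Foxp3GFP (-0.15), Mzb1 in Foxp3CNS1- (-0.28) and Jchain by genotype in colonized (-0.013), since few cells held their UMIs.

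Leiden classes gave other shares. At resolution 0.5 Treg-like cells were 43.0% of germ-free and 41.0% of colonized Foxp3GFP and 43.7% of germ-free Foxp3CNS1-, and naive-like cells were 39.7%, 28.1% and, in colonized Foxp3CNS1-, 23.5%. At resolution 2 Treg-like cells were 40.7% and 33.1% of germ-free and colonized Foxp3GFP and 38.1% and 33.9% of Foxp3CNS1-, and naive-like cells were 24.8% and 20.6% of colonized Foxp3GFP and Foxp3CNS1-. The order of the libraries in Treg-like share was therefore not kept.

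The IL-2/STAT5, exhaustion and Th2 lists, and the Tfh list under colonization, were not followed. Some other settings gave no value. Scrublet marked too few cells, no class held a proliferating cluster, the other denominator applied to cluster sizes that were not compared, and settings for normalized values did not apply to counts. At the minimum of 200 UMIs, 123 named ratios had no value. No paired analysis was possible because the labels tie no samples across groups and no result comes from a test. Depth limits genes of few UMIs, whose intervals span several log2 units.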

Other observations

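The test of Cdk5rap1 was chosen after the result was seen. Holding the list members fixed in the tests of cluster 5 was also decided after a value had been seen.

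Interferon-stimulated genes were higher after colonization in both genotypes and both named classes. The lowest of the 4 list medians was 0.98. It stayed at 0.96 after every cell was thinned to one depth, above the random range, whose highest upper end was 0.08, which argues against depth as the cause. It was 0.86 without cells holding a B cell UMI, so those cells were not the whole cause. This left out 2434 of 3979 germ-free and 2673 of 4030 colonized Foxp3GFP cells. In Foxp3CNS1- it left out 2175 of 3533 and 3652 of 5406. RNA of B or plasma cells can also be present where no such UMI was counted, so the setting cannot exclude it. Without cells holding an Hspa1a or Hspa1b UMI the lowest median was 0.95, so those cells were not the whole cause. They were 9.95% of colonized Foxp3GFP and 8.84% of colonized Foxp3CNS1- cells. Stressed cells without such a UMI stayed in, so handling stress of a whole library cannot be told apart. A response to the microbiota may underlie the pattern, but each group is 1 library, so a difference between batches cannot be told apart from colonization.

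In cluster 5 the induced Treg list had a lower colonization ratio in Foxp3CNS1- than in Foxp3GFP, by -1.34, while in Treg-like cells the difference was -0.046, inside its random range. After thinning it was -0.87 over all 5 members, with a spread of 0.31. That lay below the random range, which ended at -0.45, and argues against depth alone. The range was drawn for the fewer members above the count minimum, on which the difference was -1.10. With the mix of second clusters held fixed it was -1.07, and among cells with no Foxp3 UMI it was -1.26. Neither cleared its bound of -1.01 by more than the spread, and on the members above the count minimum the latter was -0.42, so a different cell mix cannot be told apart from a difference within cells. Among cells with a Foxp3 UMI the difference was -0.98, with Ccr9 going the other way. The -1.26 and the -0.98 were both the value of Gzmb. It had 0 UMIs in germ-free Foxp3GFP in both sets of cells, so its Foxp3GFP ratio stood at the floor. The genotype itself may contribute and was not tested. With all genes of at least 1 UMI the list median of the difference was -0.26, inside its random range.

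Cdk5rap1 (mm10 chromosome 2, 154335380 to 154373010) was low in the colonized Foxp3GFP library in each class. Its log2 ratio to the other 3 libraries was -2.49 in Treg-like, -2.22 in naive-like and -3.34 in cluster 5 cells, with overlapping intervals. That library had the highest median UMIs per cell, 2832, so a lower depth does not apply. A variant or allele carried by the pooled mice is a candidate explanation, since it would lower the gene alike in every class, with -2.22 as the highest of the 3 values. Other causes shared by that whole library would do the same and were not separated from it.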
